A study of Rattus norvegicus with 27 samples.

How the data were processed

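The samples were motor neurons of the tail, taken from the sacral spinal cord of adult male Wistar rats. Per the labels' protocols, the spinal cord was transected at S2 with removal of a short piece of tissue, or the rats had a sham operation in which the vertebrae were opened and the dura was left intact. The neurons were labelled by the retrograde fluorescent tracer Fluorogold, injected 5 to 7 days before the cords were frozen. Labelled neurons were laser-dissected from sections of 10 µm. The sample labels give 100 to 200 neurons per sample and the series design text gives 50 to 200. Per the labels, total RNA was amplified in 2 rounds and hybridised to Affymetrix rat expression arrays. The cords were taken 21 or 60 days after the operation. Each sample is numbered as a biological replicate in the labels. The labels do not tie a sample to an animal, litter, dissection day or hybridisation batch, so the p-values measure the spread between these samples.

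The deposited values are log2 probe set signals. Per the submitters' processing notes they were made by RMA, a method that corrects background, normalizes arrays to one another and summarises the probes of each set. The version of RMA and the rule by which probe sets entered the table are not given in the sources used here. The table held 12919 probe sets with values between 0 and 14.6, and the medians of the 27 arrays lay between 6.31 and 6.41. No centring per probe set was seen, and the values were read as a log2 scale from their range and from the RMA label. All 27 columns were matched to a sample by name. The highest correlation of any pair of arrays was 0.989 and the lowest 0.825, and 0 pairs held identical values. Arrays have no count depth, so precision is limited by the number of arrays per group.

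Gene names came from the platform annotation supplied with the table. Of the 12913 tested probe sets, 11880 had 1 gene symbol, 320 had several and 713 had none listed. Probe sets with several symbols were not named. The gene identifiers of 11849 single-gene probe sets were found in a RefSeq gene table, which changed 0 symbols. These probe sets covered 9769 genes, 1705 of them with more than 1 probe set. For gene-level statements the probe set with the highest mean over all arrays stood for the gene, and other probe sets of named genes were tested as an alternative. No genome was used here, so no coordinates are given.

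Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings) on the deposited log2 values. One fit held the 27 arrays in 4 groups without covariates, and the groups shared 1 estimate of the spread. The 6 control probe sets for beta-actin and GAPDH were left out of the fit, and no filter on signal was applied. The 6 contrasts were transected minus sham at 21 days, the same at 60 days, the mean of both, the difference between both, and 60 minus 21 days within each operation. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 12913 probe sets, and 0.05 was the threshold for the adjusted p. Errors given as ± after a log2 difference are standard errors of the fit.

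In all, 36 gene lists were tested in each of the 6 comparisons: 7 lists of markers of other cell types and 29 lists of pathways, channels, receptors and complexes. The test was camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Beside it stand camera with an estimated correlation and fry, whose directional test asks whether the genes of a list move on balance one way and whose mixed test asks whether they move either way. Fry does not compare a list with the other genes, so many lists can pass where a large share of all probe sets passes. The samples, contrasts, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names up to 10 genes per direction with the largest difference among those past the threshold for 21 days, 60 days and their mean, up to 5 per direction for the comparisons between days, up to 4 members with the smallest p of each list called by camera, and a fixed set (Slc18a3, Htr2a, Htr2b, Htr2c, Cacna1c, Cacna1d, Gfap, Aif1 and Mbp). Chat and Slc12a5 belonged to that set but had no single-gene probe set in the annotation used. Where no gene passed, the 5 with the smallest p per direction are given as values. Other list members are given as examples.

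Array quality was measured by the 3' minus 5' and 3' minus middle differences of the beta-actin and GAPDH controls and by the mean of each marker list of another cell type. Transected and sham arrays of each day were compared by a two-sided exact permutation test, adjusted over a family of 22 tests, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Plots were made with matplotlib 3.10.9. The hybridisation and poly-A spike controls were not analysed here.

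The limma steps were tested on simulated data with 100 changed probe sets per size among 12913. The simulated noise was independent between probe sets and between arrays, and no array stood apart. The shares below therefore need not hold for the deposited values. At 21 days, 43% of changes of 0.5 log2 and 91% of changes of 1 log2 were recovered, with 2.9% false among the calls. At 60 days the shares were 40% and 93%, with 2.92% false. For the mean of both days they were 77% and 99%, with 3.83% false. With no change put in, 0 probe sets were called. In the simulated list test, a list of 61 genes shifted by 0.3 log2 was recovered and 1 other list without a shift was called too.

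Alternatives fixed in advance were median centring and quantile normalization of the arrays, filters on mean signal, trended and robust eBayes, array weights, fits of only the groups compared, 1 probe set per gene or every single-gene probe set, the replicate number as a block, the mean of glial markers as a covariate, the 3' minus 5' control difference as a covariate for counts, and leaving out each array in turn. Added after the data had been seen were fits without sham replicates 1 and 4 of day 60, fits with 21-day transected replicates 1 to 4 or 5 to 8 left out, the 3' minus 5' covariate for named genes and lists, the ribosomal list without S6 kinases, and leaving out each array in turn for list members that had passed.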

Results

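Gene expression was measured in laser-dissected tail motor neurons of adult rats after transection of the sacral spinal cord, which separates these neurons from the brain, or after a sham operation. The 27 arrays comprised 6 sham and 8 transected samples at 21 days and 5 sham and 8 transected samples at 60 days. Values are log2 signals after RMA, and differences are transected minus sham unless stated. The design asks which transcripts of motor neurons differ after transection at each time and whether the effect differs between the times.

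Transected and sham arrays separated completely on the first principal component, which held 33.9% of the variance and on which the sham arrays lay between 5.26 and 52.3 and the transected arrays below 0. Sham replicates 1 and 4 of day 60 stood apart from the other sham arrays, with first-component scores of 40.1 and 52.3 and second-component scores of 15.1 and 40.7. In sham replicate 4 of day 60 the mean of the motor neuron identity genes was 8.24, against 9.49 in the nearest of the other 60-day sham arrays. Sham replicate 1 of day 60 had the highest oligodendrocyte marker mean of its group, 8.77, against 7.77 in the nearest array.

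**Figure D1:**
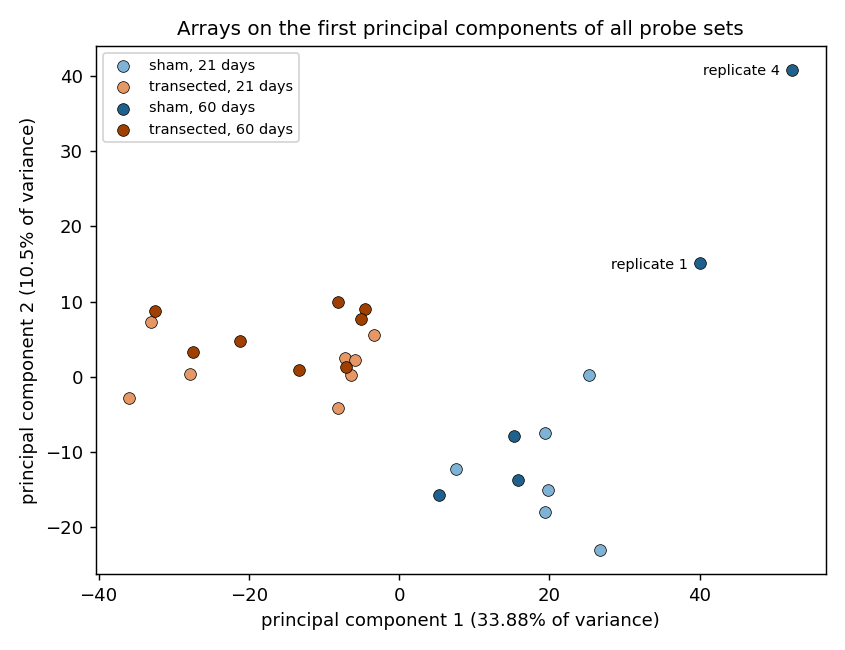
Each point is 1 array on principal component 1 (33.88% of variance) and principal component 2 (10.5%), coloured by operation and day, and the 2 labelled points are sham arrays of day 60. The sham arrays lie to the right of 0 on component 1 and the transected arrays to the left.

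The control probe sets also differed between operations. The beta-actin 3' minus 5' difference is used as a sign of transcripts shortened toward their 3' end, but a higher 3' signal raises it. The difference was 3.21 ± 0.285 (SD, n = 8) in transected and 2.28 ± 0.229 (SD, n = 6) in sham arrays at 21 days. Its difference of 0.92 log2 had an exact permutation p = 0.000666 and adjusted p = 0.00855 over 22 tests. At 60 days the difference was 1.05 log2 (exact permutation, adjusted p = 0.00855), and that of the GAPDH controls was 0.81 log2 (exact permutation, adjusted p = 0.0137). The mean beta-actin 3' signal was higher after transection (9.28 against 8.13 at 21 days, 9.29 against 8.13 at 60 days). The mean 5' signal was not lower (6.07 against 5.85, and 6.03 against 5.92). These 5' means lay below the medians of the arrays (6.31 to 6.41), where a fall may not show. The beta-actin differences therefore do not decide whether transcripts were shortened. At 21 days the GAPDH 3' minus 5' difference was −0.84 log2, which did not pass (exact permutation, adjusted p = 0.182). There the transected arrays fell into separate ranges, 2.57 to 3.47 in replicates 1 to 4 and 0.985 to 1.46 in replicates 5 to 8. The labels give no batch. The marker means of 7 other cell types did not pass in the exact permutation tests; the smallest p was that of blood cell markers at 60 days, −0.32 log2 (exact permutation p = 0.0482, adjusted p = 0.141).

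At 21 days after transection, Apoe, which encodes a lipid carrier, rose 5.27-fold in the limma fit (log2 difference 2.40 ± 0.239, adjusted p = 2.23e-07), and Cacng2, an auxiliary subunit of AMPA receptors, rose 4.87-fold (2.28 ± 0.259, adjusted p = 1.53e-06). Clcn3, a chloride/proton exchanger, rose 4.60-fold and Sptbn4, a spectrin of the axon initial segment, rose 3.28-fold. For each of these 4 genes the 8 transected arrays lay above every sham array of the day. Among these transected arrays Apoe was highest where the astrocyte gene Gfap was highest (replicate 4, 8.94 and 11.8). It was lowest where Gfap was lowest (replicate 8, 7.51 and 8.79). Sham replicate 6 of the day went the other way, with more Gfap (10.3) but less Apoe (6.39) than transected replicate 8. Whether the Apoe RNA came from the motor neurons was not tested. Arg1, the enzyme arginase, fell by 2.96 ± 0.66 on the log2 scale, 7.78-fold (adjusted p = 0.00264, below the sham mean of the day in 7 of 8 transected arrays and below every sham array in 7), and Scn9a, a voltage-gated sodium channel, fell by 2.31 ± 0.444 (adjusted p = 0.000794, below the mean in 8 and below every sham array in 6 of 8). The injury-response transcription factor Atf3 fell by 1.77 ± 0.543 (adjusted p = 0.0211, below the mean in 8 and below every sham array in 6 of 8), from 10.7 ± 0.916 (SD, n = 6) in sham to 8.93 ± 0.896 (SD, n = 8) in transected arrays.

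In all, 2917 of 12913 probe sets passed at 21 days, 22.6%, with 1465 higher and 1452 lower. Of these, 55 were over 2-fold higher and 157 over 2-fold lower. The other named genes that rose were Sympk, Adgrb2, Zfp771, Dapk3, Pcsk1n and Cdh13, with log2 differences from 1.40 to 2.01. The other named genes that fell were Reg3b (−2.57 ± 0.87), Tm4sf1 (−2.31), Ccar1 (−2.02), Bhlhe22 (−1.93), Cd55 (−1.93), Eif1a (−1.80) and Phip (−1.65). The second probe set of Ccar1 went the other way, 0.32 (adjusted p = 0.0387), and that of Cd55 differed by −0.07 (adjusted p = 0.738). The second probe set of Phip (−0.43, adjusted p = 0.173) and that of Cdh13 (0.47, adjusted p = 0.129) did not pass. Reg3b lost its call without any of 6 single arrays (adjusted p up to 0.0718), with differences from −2.88 to −2.17 over all such fits. Atf3 did without 21-day sham replicate 1 or 4 (adjusted p up to 0.0627), with −1.97 to −1.54. With the replicate block Reg3b did not pass either (−2.76, adjusted p = 0.0526).

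**Figure D2:**
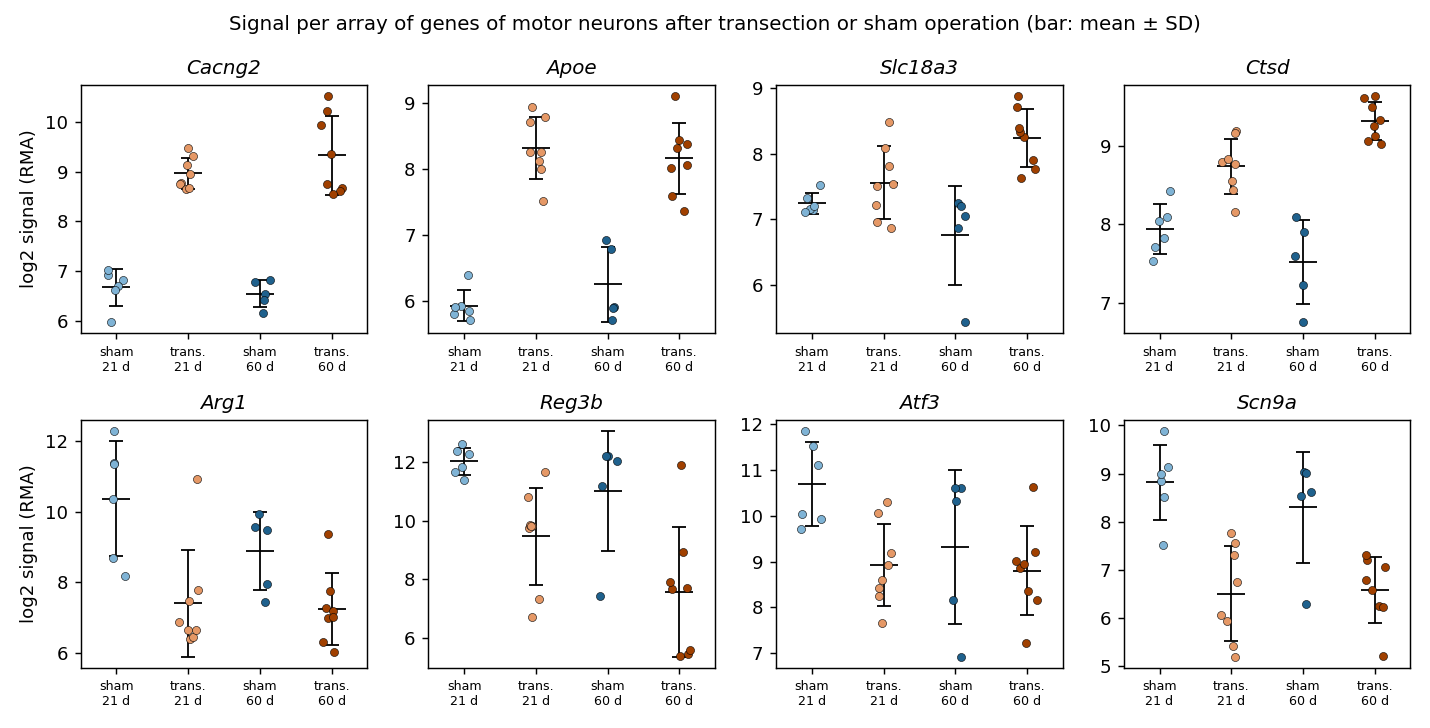
Log2 RMA signal of 8 named genes, 1 point per array, in sham and transected (trans.) arrays at 21 and 60 days; the bar is the mean and the whiskers are the SD. For Cacng2 and Apoe every transected array lies above every sham array of its day, while 1 sham array of day 60 lies far below the others for Slc18a3, Reg3b and Scn9a.

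At 21 days 22.6% of all probe sets passed, and the counts of list members below are to be read beside this share. Among ion channels, 4 of 19 measured genes on the voltage-gated calcium channel list rose and 1 fell, also when adjusted over the list alone. This list also holds Cacng genes, among them Cacng2, the auxiliary subunit of AMPA receptors. Beside Cacng2, the risers were Cacna1i (0.39), Cacna1b (0.35) and Cacna1g (0.29), and Cacnb4 fell by 0.74. Cacna1d (−0.32, adjusted p = 0.0837) and Cacna1c (−0.18, adjusted p = 0.317) did not pass. Cacna1d did without 21-day transected replicate 6 (−0.40, adjusted p = 0.0196), without 60-day sham replicate 4 (adjusted p = 0.0438) or 1 and 4 (adjusted p = 0.0472), and with array weights (−0.34, adjusted p = 0.0334). Of 10 sodium channel and channel-partner genes 1 rose, Fgf12 (0.49), and 1 fell, Scn9a, and 1 and 2 adjusted over the list alone; the median of this list was 0.03 and its mean −0.31, and camera gave it as lower without a call (adjusted p = 0.884). Of 61 potassium channel genes 6 rose, such as Kcnh2 (0.42) and Kcna2 (0.33), and 4 fell, such as Kcnc2 (−1.27) and Kcnab1 (−0.80); adjusted over the list alone the counts were 5 and 2. Kcnc2 lost its call without any of 8 single arrays (−1.41 to −1.07, adjusted p up to 0.11) and Kcna2 without sham replicate 1 (0.30, adjusted p = 0.0589). Of 22 ionotropic glutamate receptor and scaffold genes 5 rose, led by the NMDA receptor subunit Grin3b (1.14 ± 0.16), and 2 fell, among them the AMPA receptor subunit Gria4 (−0.97 ± 0.169), with the same counts adjusted over the list alone. Of 33 monoamine and acetylcholine receptor genes 6 rose and 1 fell, and 5 and 1 adjusted over the list alone. The one that fell was the serotonin receptor Htr2b (−0.57 ± 0.178, adjusted p = 0.0224, lost without 21-day sham replicate 1 at −0.42 and adjusted p = 0.0862). Htr2a (0.02, adjusted p = 0.902) and Htr2c (−0.02, adjusted p = 0.905) did not pass. Without 1 array at a time 3 to 7 potassium channel genes rose and 2 to 5 fell, 2 to 7 monoamine and acetylcholine receptor genes rose and 0 to 1 fell, and 1 to 3 sodium and 1 to 2 calcium channel genes fell.

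Of 22 axon injury and regeneration genes at 21 days, 5 fell and 2 rose, also when adjusted over the list alone. Beside Arg1 and Atf3, the neuropeptide gene Vip (−1.34), Plat (−0.62) and Smad1 (−0.50) fell, while Basp1 (1.09) and Tubb3 (0.70), which encode a growth cone protein and a neuronal tubulin, rose. Single arrays ended the calls of Vip (12 arrays, adjusted p up to 0.16, with −0.895 without sham replicate 4), Smad1 (6 arrays, −0.58 to −0.38, adjusted p up to 0.126) and Tubb3 (4 arrays, 0.59 to 0.77, adjusted p up to 0.0653). Of 22 synaptic vesicle and release genes 6 rose, such as Syp (0.64) and Napa (0.47), and 1 fell, with the same counts adjusted over the list alone. Of 17 motor neuron identity genes 2 rose and none fell, and 1 rose adjusted over the list alone; Slc18a3, the vesicular acetylcholine transporter, differed by 0.32 (adjusted p = 0.388). Slc18a3 read 7.51 to 8.49 in transected replicates 1 to 4 and 6.87 to 7.53 in replicates 5 to 8, beside 7.11 to 7.52 in sham arrays. Its mean difference thus joins 2 unlike sets of transected arrays. Of 31 neurotrophic factor and receptor genes 4 rose, among them Nrg1 (1.32) and Ntrk2 (0.70), and 3 adjusted over the list alone. Of 21 heat shock genes 2 rose and 6 fell, such as Hspa4 (−0.86) and Dnaja1 (−0.76), and 2 and 8 adjusted over the list alone. Without 1 array at a time 2 to 5 injury genes fell and 1 to 3 rose, 3 to 6 synaptic genes rose and 0 to 1 fell, 1 to 2 identity genes rose and 0 to 4 fell, and 1 to 2 heat shock genes rose and 5 to 8 fell.

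Cholesterol biosynthesis was the list that passed camera at 21 days (lower, median −0.40, adjusted p = 0.0123), and it did not pass with an estimated correlation (adjusted p = 0.89). Of its 17 members 7 fell and 1 rose, and 10 and 1 adjusted over the list alone. The sterol enzyme gene Msmo1 (−0.81 ± 0.145), Acat2 (−0.89 ± 0.204), Stard4 (−0.53 ± 0.138) and Sqle (−0.65) fell, and Srebf2, a transcription factor that activates this pathway, rose by 0.51 ± 0.13. With fry, which does not compare a list with the other genes, 4 of the 36 lists passed in 1 direction and 25 passed in the mixed test. Among markers of other cells, 4 of 16 astrocyte genes rose, such as Gfap (1.07 ± 0.335, adjusted p = 0.0234) and Aldoc (0.92), and 1 fell, also adjusted over the list alone. Without 1 array at a time 2 to 4 astrocyte genes rose. Gfap lost its call without 21-day sham replicate 1 or 2 (0.96 and 1.00, adjusted p up to 0.0618). Mbp, a myelin gene, rose by 1.08 ± 0.389 (adjusted p = 0.0453), a call that 13 single arrays could end (0.80 to 1.43, adjusted p up to 0.148), as did array weights (1.01, adjusted p = 0.0648) and the replicate block (1.12, adjusted p = 0.0667). Of its 2 other probe sets 1 passed (0.47, adjusted p = 0.0143) and 1 did not (0.34, adjusted p = 0.0909). Aif1, a microglial gene, differed by −0.89 (adjusted p = 0.106) and passed with the glial covariate (−1.21, adjusted p = 0.00538) and without 21-day transected replicate 4 (−1.18, adjusted p = 0.0179). The glial covariate holds Aif1 itself, so the pass with it is not independent support.

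Fits with only part of the transected arrays of day 21 gave different counts. With replicates 5 to 8 left out 3903 probe sets passed, of which 2424 were among the 2917, and with replicates 1 to 4 left out 1335 passed, of which 1097 were. Between these fits, 829 probe sets passed in both in the same direction and 7 in opposite directions, and the log2 differences correlated at r = 0.664 across probe sets, which share the sham arrays and are not independent replicates. These subsets were chosen after the control values had been seen. With only the probe sets above the median of mean signal 1811 passed, with 699 higher and 1112 lower.

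At 60 days after transection, Cacng2 rose 6.85-fold (log2 difference 2.78 ± 0.273, adjusted p = 1.43e-07) and Clcn3 rose 5.33-fold (2.41 ± 0.27, adjusted p = 1.06e-06) in the limma fit. Apoe rose 3.77-fold and the lysosomal protease Ctsd rose 3.47-fold (1.80 ± 0.193, adjusted p = 5.79e-07). Slc18a3 rose 2.79-fold, from 6.76 ± 0.756 (SD, n = 5) to 8.24 ± 0.444 (SD, n = 8, limma adjusted p = 0.000434). In each of these 5 genes the 8 transected arrays lay above every sham array. Reg3b, a secreted lectin, fell by 3.46 ± 0.919 on the log2 scale (adjusted p = 0.00973, below the sham mean of the day in 7 of 8 transected arrays and below every sham array in 3), and Scn9a fell by 1.72 ± 0.469 (adjusted p = 0.0117, below the mean in 8 and below every sham array in 3 of 8).

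At this time 2463 probe sets passed, 19.1% of those tested, with 1311 higher and 1152 lower, and 89 were over 2-fold higher and 195 over 2-fold lower. The further named genes that rose were Sympk, Zfp771, Pcsk1n, Slc45a1, Adgrb2 and Cdh13, by 1.74 to 2.03 log2. Those that fell were Bhlhe22 (−2.15), Ccar1 (−2.04), the sodium channel subunit gene Scn3b (−1.93), Cdkn3 (−1.88), Eef1a1 (−1.81), which encodes a translation elongation factor, Mospd2 (−1.79), Rapgef4 (−1.78) and Fmr1 (−1.70). The second probe sets of Scn3b (−0.88, adjusted p = 0.103), Eef1a1 (−0.72, adjusted p = 0.14) and Ccar1 (0.20, adjusted p = 0.223) did not pass. Without sham replicate 4 of day 60, where Scn3b read 12.7 against at most 9.65 in the other 60-day sham arrays, its difference was −1.25 (adjusted p = 0.0247).

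Of 45 cytosolic ribosomal protein genes on the list at 60 days, 15 fell and 3 rose, and 17 and 3 adjusted over the list alone. This list passed camera (lower, median −0.19, adjusted p = 0.000936) and did not with an estimated correlation (adjusted p = 0.96). Rpl35a (−0.72 ± 0.0949), Rpl21 (−0.84 ± 0.113), Rpl24 (−0.82 ± 0.151) and Rpl23a (−0.78 ± 0.158) fell, and Rps15 rose by 0.42. The list pattern also took in 3 ribosomal S6 kinase genes, which are not ribosomal proteins; without them 14 of 42 members fell and 3 rose. No other list passed camera. With fry 8 lists passed in 1 direction, and 26 in the mixed test. Of 74 oxidative phosphorylation genes 15 rose, such as Uqcrc1 (1.57), Cox6a1 (1.26) and Cox4i1 (1.04), and 8 fell, such as Ndufaf5 (−0.55); adjusted over the list alone the counts were 18 and 9. Without sham replicate 4 of day 60, 9 of these rose and 6 fell, and without 1 array at a time 9 to 18 rose and 6 to 10 fell. The ribosomal counts were 1 to 3 higher and 11 to 17 lower in such fits.

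Of the 17 motor neuron identity genes 4 rose at 60 days and none fell, and 5 rose adjusted over the list alone. They were Slc18a3, the neurofilament gene Nefh (0.38), the intermediate filament gene Prph (0.92) and the nicotinic receptor subunit gene Chrna4 (0.35). Sham replicate 4 of day 60, with its low mean of these genes, moved with this. Without it the list median was −0.05 instead of 0.23 and the mean 0.03 instead of 0.31. Then 2 members rose, Slc18a3 (1.15, adjusted p = 0.00219) and Chrna4 (0.36, adjusted p = 0.0476), and Calca fell (−0.98, adjusted p = 0.0247), while Nefh (0.17, adjusted p = 0.167) and Prph (0.30, adjusted p = 0.121) did not pass. Other single arrays also ended the calls of Nefh, Prph and Chrna4 (4, 13 and 3 arrays in all; 0.29 to 0.38 and adjusted p up to 0.0994 for Chrna4). Of 20 axonal transport motor genes 6 rose, such as Dctn6 (0.79) and Dctn1 (0.75), and 2 fell, Dctn5 (−0.70) and Dync1i2 (−0.66); adjusted over the list alone the counts were 8 and 2. Of 61 potassium channel genes 9 rose, among them Kcna1 (0.97) and Kcnk3 (0.71), and 3 fell, among them Kcna4 (−1.16), and 10 and 4 adjusted over the list alone. Of 10 sodium channel genes 3 fell, Scn3b, Scn9a and Scn2a (−0.93), and 1 rose, Scn10a (0.37); adjusted over the list alone 3 fell and 2 rose. Without sham replicate 4 Scn3b (−1.25) and Scn2a (−0.54, adjusted p = 0.0448) differed less, and Scn10a lost its call without any of 3 single arrays (0.30 to 0.42, adjusted p up to 0.0867). Of 19 genes on the calcium channel list 3 rose, Cacng2 and Cacng7 among them, and 1 fell, also adjusted over the list alone. The one that fell was Cacna1d (−0.54 ± 0.141, adjusted p = 0.00885), whose call was lost without sham replicate 4 (−0.38, adjusted p = 0.0531). Of 22 glutamate receptor genes 4 rose, led by Grin3b (1.25), Grik5 (0.76) and Grin1 (0.69), and 2 fell, Gria2 (−1.02) and Gria4 (−0.57); adjusted over the list alone the counts were 5 and 2. Gria2 lost its call without any of 7 single arrays (−0.38, adjusted p = 0.144 without sham replicate 4) and Gria4 without any of 3 (−0.61 to −0.50, adjusted p up to 0.069). Of the 22 injury genes 4 rose, among them Basp1 (0.89) and Tubb3 (0.92), and 1, Vip (−1.61, lost without sham replicate 2 or 4 at −1.17 and −1.49, adjusted p up to 0.11), fell, also adjusted over the list alone; the median of this list was −0.04 and its mean −0.08, while camera gave it as higher without a call (adjusted p = 0.935). Without sham replicate 1 of day 60, and also without sham replicate 4, 2 injury genes rose. Without 1 array at a time 6 to 10 potassium channel genes rose and 1 to 4 fell. In such fits 2 to 4 genes of the calcium channel list rose and 0 to 2 fell, and 0 to 2 sodium channel genes rose. Of glutamate receptor genes 3 to 5 rose and 0 to 3 fell, and 0 to 2 injury genes fell.

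Htr2b (−0.23, adjusted p = 0.41), Htr2a (0.08, adjusted p = 0.609), Htr2c (0.09, adjusted p = 0.522) and Cacna1c (−0.19, adjusted p = 0.348) did not pass at 60 days. Among other cell types, 2 of 16 astrocyte genes rose, Aldoc (1.38) and Slc7a10 (0.30), and 2 fell, Acsl3 (−0.89) and Vim (−1.53); adjusted over the list alone 3 rose and 2 fell. Vim lost its call without any of 5 single arrays (−0.91, adjusted p = 0.179 without sham replicate 1) and Slc7a10 without any of 3 (0.27 to 0.33, adjusted p up to 0.0846). Without 1 array at a time 1 to 4 astrocyte genes rose and 1 to 3 fell, and 1 to 3 blood cell markers fell. The astrocyte list had a median of −0.04 and a mean of −0.10, while camera gave it as higher without a call (adjusted p = 0.963). Gfap (0.65, adjusted p = 0.196), Mbp (1.04, adjusted p = 0.0745) and Aif1 (−0.61, adjusted p = 0.321) did not pass. Mbp did without 60-day sham replicate 1 (1.55, adjusted p = 0.00491), without sham replicates 1 and 4 of day 60 (1.68, adjusted p = 0.01), without 21-day sham replicate 6 (adjusted p = 0.0441), with array weights (1.39, adjusted p = 0.00901) and with the glial covariate (0.87, adjusted p = 0.00295), but its 2 other probe sets did not (0.36, adjusted p = 0.0786, and 0.14, adjusted p = 0.54). The glial covariate holds Mbp itself, so the pass of Mbp with it is not independent support. Of 7 blood cell markers 1 fell, the haemoglobin gene Hbb (−1.38), and 2 adjusted over the list alone. Sham replicate 1 of day 60 had the highest blood marker mean of its group, 7.075, and read 10.42 for Hbb; without it Hbb differed by −0.90 (adjusted p = 0.0236).

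The count at 60 days moved with the sham arrays that stood apart and with the control probe sets. Without sham replicate 1 of day 60, 1635 probe sets passed, and without sham replicate 4, 1538 passed, of which 1457 were among the 2463. Without sham replicates 1 and 4, 797 passed (472 higher and 325 lower), and 728 were among the 2463; Bhlhe22 (−1.58, adjusted p = 0.0547), Fmr1 (−1.14, adjusted p = 0.0604), Rapgef4 (−0.80, adjusted p = 0.26) and Cacna1d (−0.39, adjusted p = 0.118) then did not pass, and Mbp did (1.68, adjusted p = 0.01). With the mean 3' minus 5' control difference as a covariate, which differed between the operations by 0.93 log2 at 60 days, 98 passed at 60 days (73 higher and 25 lower), 88 of them among the 2463. Its values did not overlap there (2.16 to 2.67 in sham and 3.05 to 3.68 in transected arrays). The covariate can therefore take away part of an effect of the operation, and this fit cannot tell the 2 apart. The median size of the 2463 differences was 0.58 without and 0.354 with the covariate, and the standard error was 1.48 times as large. Cacng2, Clcn3, Sympk, Apoe, Zfp771, Ctsd, Adgrb2, Ccar1 and Rpl21 passed with the covariate. The other 17 named genes that had passed at 60 days did not, with adjusted p from 0.0917 for Rpl35a to 0.635 for Cacna1d. For 5 of them the difference kept at least 0.8 of its size and the larger standard error ended the call: Reg3b (−3.25 ± 1.4), Scn3b (−2.19 ± 0.712), Bhlhe22 (−1.90 ± 0.75), Eef1a1 (−1.60 ± 0.512) and Rpl24 (−0.68 ± 0.226). For 10 it fell below 0.6 of its size, as for Slc18a3 (0.63 ± 0.345, adjusted p = 0.435) and Cdkn3 (−0.75 ± 0.498, adjusted p = 0.545). The ribosomal list did not pass either (−0.125, adjusted p = 0.0803). At 21 days this covariate differed by 0.0424, the mean of opposite actin (0.92) and GAPDH (−0.84) differences, so it changed little there (r = 0.999 with and without it) and does not test the 21-day count.

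Over both days, 1318 probe sets passed at 21 and at 60 days: 652 higher on both, 664 lower on both and 2 in opposite directions. Independent lists of these sizes would share 149 higher and 129.5 lower. Of the probe sets that passed at 21 days, 95.4% had the same sign at 60 days. The log2 differences of both days correlated at r = 0.775 (Spearman's rho 0.726) across probe sets, which are not independent replicates. The days have sham arrays of their own.

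**Figure D3:**
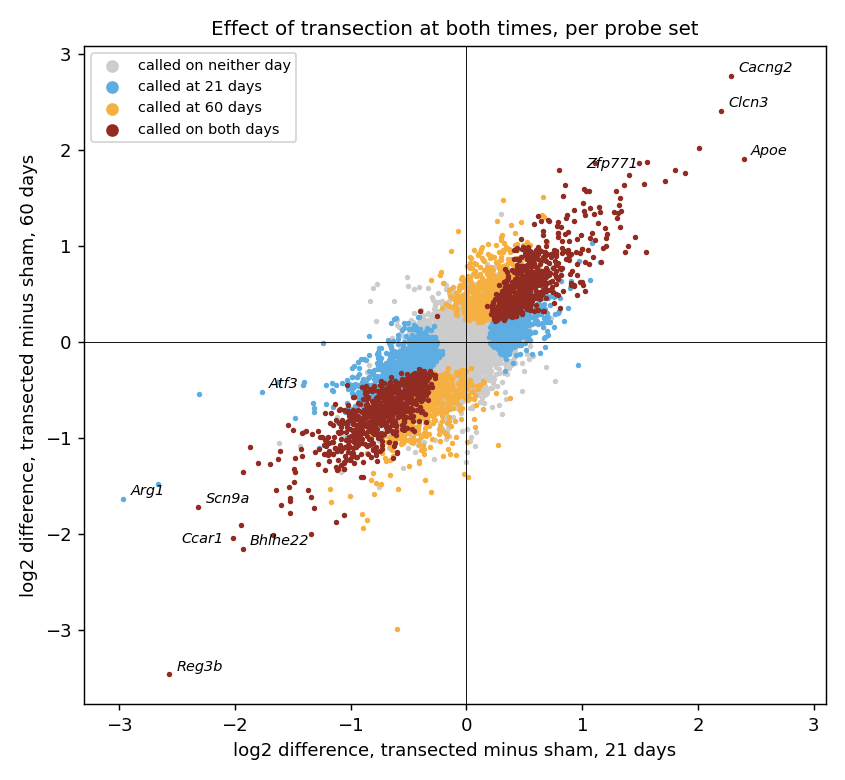
Each point is 1 probe set, with its log2 difference between transected and sham arrays at 21 days on the horizontal axis and at 60 days on the vertical axis. Probe sets that passed on both days (1318) lie in the lower left and upper right, with 2 exceptions, and r across probe sets was 0.775.

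Averaged over both days, Cacng2 rose 5.77-fold (log2 difference 2.53 ± 0.188, limma adjusted p = 2.21e-10) and Clcn3 4.95-fold, followed by Apoe, Sympk, Adgrb2, Zfp771, Sptbn4, Pcsk1n, Dapk3 and Cdh13 with 1.57 to 2.16 log2. For each of these 10 genes the 16 transected arrays lay above every sham array of their day. Reg3b fell by 3.01 ± 0.633 (adjusted p = 0.000553, below the sham mean of their day in 15 of 16 transected arrays and below every sham array in 10) and Arg1 by 2.30 ± 0.48 (adjusted p = 0.000522, below the mean in 14 and below every sham array in 13), and Bhlhe22, Ccar1, Scn9a, Rapgef4, Fmr1, Cd55, Phip and Dcun1d5 fell with differences from −1.59 to −2.04. Here Slc18a3 (0.90, adjusted p = 0.00048), Gfap (0.86, adjusted p = 0.00678) and Mbp (1.06, adjusted p = 0.00445) rose, and Htr2b (−0.40, adjusted p = 0.016), Cacna1d (−0.43, adjusted p = 0.00113) and Aif1 (−0.75, adjusted p = 0.0417) fell. Htr2a (0.05, adjusted p = 0.586), Htr2c (0.04, adjusted p = 0.679) and Cacna1c (−0.19, adjusted p = 0.117) did not pass. Cacna1c did without 60-day transected replicate 5 (−0.23, adjusted p = 0.0259) and with array weights (−0.22, adjusted p = 0.0316). With the replicate block Htr2b (−0.36, adjusted p = 0.0541) and Aif1 (−0.74, adjusted p = 0.0635) did not pass, nor did Aif1 without sham replicates 1 and 4 of day 60 (−0.56, adjusted p = 0.171). The second probe set of Ccar1 passed in the other direction (0.26, adjusted p = 0.0119). Those of Cd55 (0.00, adjusted p = 0.983) and Phip (−0.38, adjusted p = 0.0682) did not pass, and of 2 others of Mbp 1 did (0.41, adjusted p = 0.00173). The call of Aif1 was lost without any of 18 single arrays (−0.89 to −0.61, adjusted p up to 0.102).

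By this average 5087 probe sets passed, 39.4% of those tested, with 2632 higher and 2455 lower. Of 285 genes whose 2 brightest probe sets both passed, 98 were higher and 115 lower on both, and 72 went in opposite directions. With the 3' minus 5' covariate 1873 passed (983 higher and 890 lower), 1748 of them among the 5087, and Slc18a3 (0.45 ± 0.208, adjusted p = 0.14), Cacna1d (−0.28 ± 0.12, adjusted p = 0.121), Gfap (0.51 ± 0.306, adjusted p = 0.266) and Mbp (0.72 ± 0.362, adjusted p = 0.181) differed less and did not pass. Htr2b (−0.43 ± 0.172, adjusted p = 0.0915) and Aif1 (−1.08 ± 0.374, adjusted p = 0.0515) differed by more and did not pass, with larger standard errors. With only the probe sets above the median of mean signal 3207 passed, 1383 higher and 1824 lower. No list passed camera, with or without an estimated correlation; the closest was that of ribosomal proteins (lower, median −0.14, adjusted p = 0.0527, and adjusted p = 0.961 with an estimated correlation), of which 17 of 45 fell and 5 rose, and 18 and 5 adjusted over the list alone; 11 to 18 fell without 1 array at a time. With fry 14 lists passed in 1 direction and 28 in the mixed test.

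**Figure D4:**
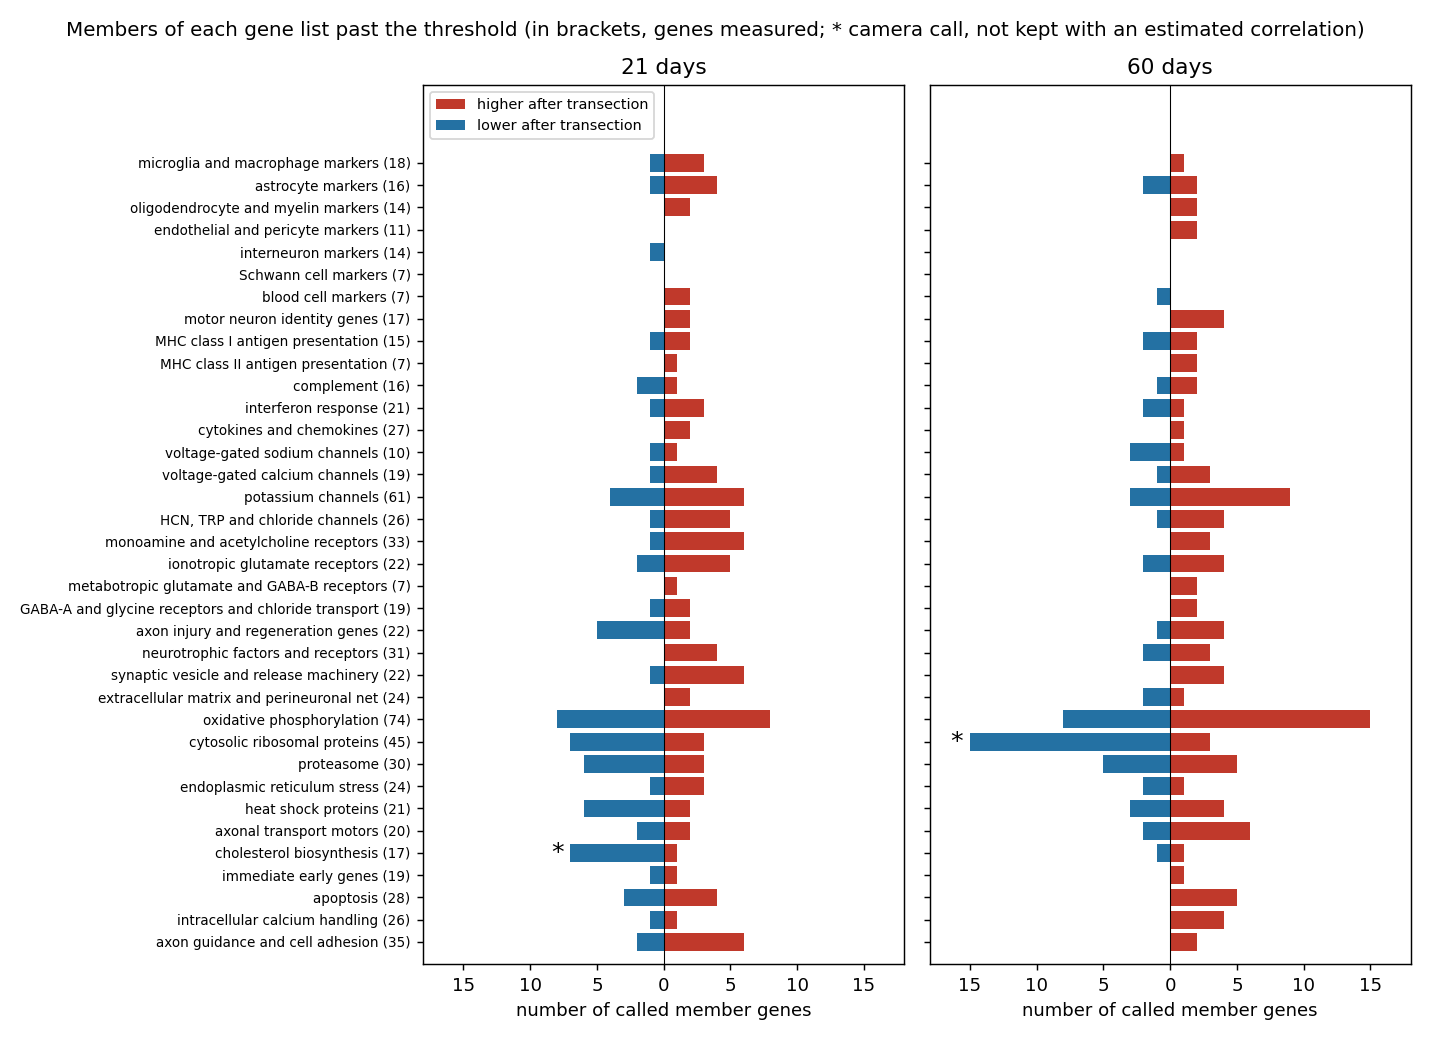
For each of 36 gene lists, with the number of measured genes in brackets, bars count the members that rose (right) or fell (left) after transection at 21 and at 60 days. The asterisk marks the list that passed camera with the preset correlation, cholesterol biosynthesis at 21 days (7 fell, 1 rose) and ribosomal proteins at 60 days (15 fell, 3 rose).

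The difference of the transection effect between days was tested as an interaction. For Ppm1g, a protein phosphatase gene, the effect was 0.72 ± 0.148 log2 higher at 60 than at 21 days, and for Igf1, a growth factor gene, it was −1.35 ± 0.304, but neither passed (limma adjusted p = 0.338 and 0.44). Fbxo36 (0.54), Lamtor4 (0.56), Arf6 (0.56), Abcc5 (0.65), Ahsp (−0.55), the ribosomal protein gene Rpl26 (−0.95), Nisch (−0.51) and Palld (−1.20) had adjusted p up to 0.627. In the limma fit 0 probe sets passed, against 905 at an unadjusted p under 0.05, and 3 passed with array weights, among them Arf6 (0.65, adjusted p = 0.0419) and Ahsp (−0.60, adjusted p = 0.0419). The 0 depended on the transected arrays used: with 21-day transected replicates 1 to 4 left out 161 probe sets passed (114 higher and 47 lower), and with replicates 5 to 8 left out 0 passed.

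Camera called 5 lists in the interaction: motor neuron identity genes (higher, median 0.48, adjusted p = 0.0013), axonal transport motors (higher, 0.24, adjusted p = 0.00255), cholesterol biosynthesis (higher, 0.31, adjusted p = 0.00322), ribosomal proteins (lower, −0.17, adjusted p = 0.0013) and blood cell markers (lower, −0.20, adjusted p = 0.0208). With an estimated correlation none passed, with adjusted p = 0.923, 0.638, 0.887, 0.977 and 0.638 in that order, and fry called 0 lists in either test. No member passed over all genes; adjusted over the list alone 1 ribosomal and 1 blood cell gene did. The members with the smallest p were Slc18a3 (1.16), Nefh (0.48), Calcb (1.27) and Nefl (0.48) among the identity genes and Dync1h1 (0.61), Dync1li1 (0.26), Dctn1 (0.35) and Kif5a (0.46) among the motors. In cholesterol synthesis they were Fdft1 (0.63), Mvd (0.63), Hsd17b7 (0.42) and Srebf2 (0.39), among ribosomal proteins Rpl26, Rpl21 (−0.49), Rpl22 (−0.61) and Rpl35 (−0.45), and among blood cell markers Hbb (−1.36), S100a8 (−0.36), Slc4a1 (−0.13) and Alas2 (−0.21). Their adjusted p lay between 0.627 and 0.859. Nefh (0.27), Nefl (0.27), Calcb (0.77) and Dctn1 (0.21) were over 1.5 times smaller without sham replicate 4 of day 60, as were Hbb (−0.88), S100a8 (−0.24) and Alas2 (−0.04) without sham replicate 1 of day 60 and Slc4a1 (−0.08) without sham replicate 6 of day 21. Single arrays ended several of these calls. Without sham replicate 4 of day 60 the identity genes (0.124, adjusted p = 0.117), the motors (0.132, adjusted p = 0.058) and cholesterol synthesis (0.239, adjusted p = 0.0964) did not pass. The blood cell list did not pass without sham replicate 1 of day 60 (−0.14, adjusted p = 0.241), sham replicate 3 of day 21 (−0.20, adjusted p = 0.0513), transected replicate 2 of day 21 (−0.18, adjusted p = 0.0519) or transected replicate 8 of day 60 (−0.11, adjusted p = 0.0535). Without sham replicates 1 and 4 of day 60 the 5 medians in that order were 0.0794, 0.138, 0.232, −0.0325 and −0.169, and none passed (adjusted p from 0.21 to 0.712). With the 3' minus 5' covariate the identity genes (0.35, adjusted p = 0.221) and the ribosomal proteins (−0.01, adjusted p = 0.495) did not pass.

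Between the days after transection, Stim1, a calcium sensor of the endoplasmic reticulum, was 0.51 ± 0.102 log2 higher at 60 than at 21 days, and Nop58, a nucleolar protein gene, fell by 0.55 ± 0.0854 (limma adjusted p = 0.0436 and 0.0075), each on that side of the 21-day mean in 8 of 8 arrays and beyond every 21-day array in 6 for Stim1 and 8 for Nop58. Neil1 (0.46), Arf6 (0.44), Gba2 (0.40) and Cadps (0.39) rose, and Palld (−1.13), Arpc5l (−0.84) and Dnajc2 (−0.58) fell, at adjusted p from 0.0436 to 0.0458. The second probe set of Stim1 went the other way, −0.06 (adjusted p = 0.853), and that of Arpc5l did not pass (−0.26, adjusted p = 0.497). With array weights Nop58 alone of these 9 genes passed, and 7 lost their call with the glial covariate (adjusted p up to 0.0684), 4 with the replicate block (adjusted p up to 0.055) and 2 with quantile normalization (adjusted p = 0.0821). In all, 11 probe sets passed, 6 higher and 5 lower, against 1706 at an unadjusted p under 0.05. No list passed camera with either correlation, fry called 0 lists in 1 direction and 2 in the mixed test. The 3' minus 5' controls differed by 0.654 log2 between these groups, and with them as a covariate 4 probe sets passed and none of the named genes did, Nop58 included (−0.51 ± 0.115, adjusted p = 0.0669). The differences of 8 of these 9 kept at least 0.8 of their size, such as Neil1 (0.44 ± 0.118), Gba2 (0.39 ± 0.109), Cadps (0.43 ± 0.107), Arpc5l (−0.75 ± 0.223) and Stim1 (0.43 ± 0.136), and Palld differed by −0.85 ± 0.293. The standard errors were 1.33 times as large. With transected replicates 1 to 4 of day 21 left out 630 passed, and with replicates 5 to 8 left out 52. The count lay between 1 (without 21-day transected replicate 6) and 83 (without 21-day transected replicate 4) when single arrays were left out, and of the named genes Nop58 alone kept its call in every such fit (adjusted p up to 0.0316), while the differences moved little, as for Stim1 (0.47 to 0.58).

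Between the days after sham operation, Igf1 differed by 1.14 ± 0.234 log2 and Chi3l1 by 1.02 ± 0.244, but no gene passed (limma adjusted p = 0.545 and 0.999). The other genes with the smallest p were Ahsp (0.40), Icam2 (0.76), Tmem179b (0.48), C2cd2 (−0.93), Cyp4a1 (−0.56), Mogat1 (−0.52), Vstm5 (−0.52) and the neurofilament gene Nefl (−0.46), with adjusted p from 0.736 to 0.999. C2cd2 (−0.59) and Nefl (−0.26) differed less without sham replicate 4 of day 60. The limma fit called 0 probe sets, against 513 at an unadjusted p under 0.05, and 2 with array weights, among them Ahsp (0.44, adjusted p = 0.0156).

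Camera called 10 lists between the sham groups. Higher at 60 days were markers of astrocytes (median 0.58, adjusted p = 2.59e-06), oligodendrocytes (0.27, adjusted p = 0.000328) and blood cells (0.29, adjusted p = 0.000265), extracellular matrix genes (0.12, adjusted p = 0.0138) and ribosomal proteins (0.09, adjusted p = 0.00211). Lower were motor neuron identity genes (−0.45, adjusted p = 5.75e-06), cholesterol biosynthesis (−0.24, adjusted p = 5.75e-06), axonal transport motors (−0.12, adjusted p = 0.00202), heat shock proteins (−0.13, adjusted p = 0.0135) and injury genes (−0.13, adjusted p = 0.015). None passed with an estimated correlation (adjusted p = 0.167 for blood cells to adjusted p = 0.724 for ribosomal proteins), and fry called 0 lists. No member passed over all genes; adjusted over the list alone 1 blood cell gene was higher and 1 motor neuron and 2 cholesterol genes were lower. The members with the smallest p had adjusted p = 0.999. They were Mlc1 (0.84), Gfap (0.94), Gjb6 (0.71) and Slc1a3 (1.16) for astrocytes, Ermn (0.75), Mog (0.40), Mal (0.29) and Cldn11 (0.53) for oligodendrocytes and Hbb (1.06), Alas2 (0.32), S100a8 (0.29) and S100a9 (0.41) for blood cells. For the matrix they were Dcn (0.79), Bcan (0.23), Col3a1 (0.45) and Fn1 (0.33), for the ribosomal list Rpl26 (0.55), Rps29 (0.23), Rpl5 (0.39) and the kinase gene Rps6kc1 (−0.24), and for identity genes Nefl, Nefh (−0.37), Calcb (−0.97) and Nefm (−0.33). For cholesterol synthesis they were Mvd (−0.56), Hsd17b7 (−0.40), Fdft1 (−0.42) and Insig1 (−0.53), and for the motors Kifap3 (−0.67), Kif5c (−0.58), Dctn2 (−0.25) and Kif5a (−0.31). For heat shock they were Hspb8 (−1.02), Bag3 (−0.43), Hspb1 (−0.47) and Dnajb1 (−0.30), and for injury Npy (0.76), Atf3 (−1.38), Stat3 (−0.67) and Arg1 (−1.49). Many of these rested on 1 array. With sham replicate 4 of day 60 left out the values were 0.40 for Slc1a3, 0.27 for S100a9, −0.26 for Nefl, −0.16 for Nefh, −0.47 for Calcb, −0.12 for Nefm, 0.26 for Npy, −0.78 for Atf3, −0.44 for Stat3, 0.14 for Bcan, 0.22 for Rpl5, −0.27 for Fdft1 and −0.34 for Insig1. They were −0.49 for Hspb8, −0.09 for Bag3, 0.00 for Hspb1, −0.35 for Kifap3, −0.33 for Kif5c, −0.10 for Dctn2 and −0.17 for Kif5a. Without sham replicate 1 of day 60 they were 0.35 for Ermn, 0.10 for Mog, 0.10 for Mal, 0.18 for Cldn11, 0.59 for Hbb, 0.15 for Alas2, 0.17 for S100a8, 0.21 for S100a9, 0.09 for Dcn, −0.04 for Col3a1 and 0.08 for Fn1. Without sham replicate 1 of day 21 Mog (0.25) and Cldn11 (0.26) were smaller, and S100a8 (0.45) was larger without sham replicate 3 of day 60 and Col3a1 (0.72) without replicate 5. Without sham replicate 4 of day 60 the identity genes (−0.0966, adjusted p = 0.0563), heat shock proteins (−0.07, adjusted p = 0.0563), motors (−0.05, adjusted p = 0.0773) and injury genes (−0.04, adjusted p = 0.179) did not pass. Without sham replicate 1 of day 60 the oligodendrocyte (0.0871, adjusted p = 0.723), matrix (0.06, adjusted p = 0.734) and injury lists (−0.08, adjusted p = 0.183) did not. The injury and matrix lists also failed without sham replicate 1 of day 21 (−0.09 and 0.14, adjusted p = 0.0893 and 0.0756), and the injury list without sham replicate 4 of day 21 (−0.13, adjusted p = 0.121). Without sham replicates 1 and 4 of day 60 together none of the 10 passed, with adjusted p from 0.0939 to 0.907, and the injury (median 0.0135) and matrix lists (−0.0219) turned direction. The median of the identity genes was then 0.0365, while camera still gave them as lower. With the glial covariate the oligodendrocyte (−0.0044, adjusted p = 0.912), matrix (0.0501, adjusted p = 0.889) and ribosomal lists (0.0361, adjusted p = 0.889) did not pass. With the 3' minus 5' covariate the injury list did not pass (−0.10, adjusted p = 0.117).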

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

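The fits with the 3' minus 5' covariate for single genes and those without sham replicates 1 and 4 of day 60 were chosen after the result was seen, as were the tests of single probe sets, of a handling difference, of single arrays behind the other injury genes and of genes that vary together.

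Many probe sets differed between transected and sham arrays, 5087 on average over both days. The glial marker mean as a covariate left 5355 past the threshold, 4894 of them among the 5087. That mean was 7.5041 in transected and 7.3423 in sham arrays at 21 days, and 7.6862 and 7.6171 at 60 days. It differed little between the operations, so this fit decides little about RNA from the marked glial cells as a source. Of the genes with both of their 2 brightest probe sets past the threshold, 25.263% had them in opposite directions, so for part of the genes the difference may lie in the part of the transcript that a probe set reads. Beta-actin 3' signals did not overlap, with a gap of 0.59053 log2 between the lowest transected and the highest sham array, and the labels give no batch, so a handling, amplification or hybridisation difference and the operation cannot be told apart. A biological effect of transection stays open too.

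Sham replicate 4 of day 60 had low motor neuron genes, with a median difference of −1.18 log2 from the other sham arrays. Of 10000 random lists matched on level, the share below a list of 22 forebrain genes was 100% (median 0.408, with Neurod1 at 2.62 and Nrgn at 2.35 but Cck at −1.02), and that below a list of 12 Hox genes was 0% (median −0.408, with Hoxd10 at −1.66). The forebrain genes were listed after the genes most different in this array had been seen and those were left out; a candidate explanation is RNA of forebrain tissue in this array, by a mixed or exchanged sample. The low Hox genes go against spinal interneurons in place of motor neurons only if these keep the Hox levels of motor neurons. No sample here measured that, and the interneuron list lay at 99.67%, so this explanation is not settled. The mean 3' minus 5' control difference of 2.2601, within the 2.1609 to 2.7884 of the 10 other sham arrays, argues against degraded RNA; no biological explanation was tested.

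Of 22 injury-response genes 6 were lower after transection and 3 higher on average over both days, while the list as a whole did not pass (median −0.02, camera adjusted p = 0.792). For Atf3 the call rested on single sham arrays, since without sham replicate 2 or 3 of day 60 its adjusted p was up to 0.0556 (difference −1.44 to −0.982 without 1 array each), although it was −1.73 (adjusted p = 0.00059) without sham replicates 1 and 4. Of the 5 other members that were lower, 4 kept their call without each array in turn, and Tubb2b did not (adjusted p up to 0.0595). With the glial marker mean as a covariate 6 of 6 kept their call. That mean differed little between the operations, so this fit decides little about RNA from glial cells. No fit held the markers of other cell types. With the 3' minus 5' covariate 3 of 6 passed and the other 3 were still lower, Atf3 (−1.40 ± 0.52) and Tubb2b (−0.66 ± 0.256) by more than before but with larger standard errors and Smad1 by less (−0.20 ± 0.158 instead of −0.38 ± 0.126). The 6 genes varied together within groups (mean r 0.344, above 99.7% of random lists, whose median was 0.0192), so they may be 1 response that differs between samples rather than 6 separate results. The random lists were matched on level alone and not on having passed, and sham replicate 4 of day 60 was kept, which limits this comparison. An injury response to the sham operation stays open.

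In 45 of 512 groups of values, 8.79%, the highest or lowest array stood apart from the others of its group; chance does so in about 1 in 20 groups. Sham replicate 4 of day 60 held 15 of them, and these groups share arrays and genes. It stood below the others of its group for Reg3b (7.427), Scn9a (6.281), Nefl (13), Slc18a3 (5.432), Acat2 (8.138), Nefh (13.17), Dync1h1 (9.9), Fdft1 (7.232), Nefm (12.54), Hspb8 (7.427), Bag3 (7.476), Hspb1 (10.74) and the mean of motor neuron identity genes (8.236), and above them for Bhlhe22 (11.85) and Npy (8.939). Sham replicate 1 of day 60 stood above its group for Mbp (11.32), Fn1 (8.175) and the means of oligodendrocyte (8.766), endothelial (6.56) and Schwann cell markers (8.706). Sham replicate 3 of day 60 had the lowest actin 3' signal of its group, 8.004, beside 8.149 in the nearest array.

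Among sham arrays of day 21, replicate 6 stood above the others for Apoe (6.388) and blood cell markers (6.341), replicate 4 for Lamtor4 (7.981) and replicate 2 for Kifap3 (8.979). Replicate 1 stood below for Clcn3 (5.853), replicate 2 for Dync1li1 (5.633) and replicate 5 for Insig1 (8.953). Among transected arrays of day 21, replicate 4 stood above for Arg1 (10.92, with a mean of 6.906 in the others), Fn1 (7.669) and microglial markers (7.414), and below for Clcn3 (7.943). Replicate 7 stood below for Slc45a1 (9.044), Hsd17b7 (6.244), Stat3 (6.535) and Bag3 (8.747) and above for Ermn (8.012). Replicate 3 stood below for Rapgef4 (2.555) and replicate 6 above for S100a8 (5.445).

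Among transected arrays of day 60, replicate 8 stood above for Aif1 (8.139) and microglial markers (7.417) and below for Hbb (6.41) and Nefm (13.41). Replicate 2 stood below for Phip (4.215). The median correlation of replicate 5 with its group was 0.9592, with 0.9687 in the nearest array.

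The effect of transection differed between the days for 5 lists by camera: motor neuron identity genes (adjusted p = 0.0013), ribosomal proteins (adjusted p = 0.0013), axonal transport motors (adjusted p = 0.00255), cholesterol biosynthesis (adjusted p = 0.00322) and blood cell markers (adjusted p = 0.0208). With an estimated correlation the adjusted p lay between 0.638 and 0.977. Without sham replicate 4 of day 60 the identity genes (median 0.124 instead of 0.48, adjusted p = 0.117), the motors (adjusted p = 0.058) and cholesterol synthesis (adjusted p = 0.0964) did not pass, without sham replicate 1 the blood cell markers did not (adjusted p = 0.241), and without both none of the 5 did. The median of the identity genes was −0.45 between the sham groups (−0.0966 without sham replicate 4 of day 60) and 0.035 between the transected groups.

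Other splits of the arrays into groups of the same sizes were fitted 100 times per comparison, the real split included. As many probe sets as the real 2917 at 21 days were called by 1 split, the real one, and the highest other gave 514. The same held for 60 days (1 split, real 2463, highest other 33) and for the average (1 split, real 5087, highest other 989). Chance is thus an unlikely source of these counts. A share of 1 in 100 is the smallest these fits can give, and it was not adjusted over the 6 comparisons. Between the days after transection, 4 splits, the real one included, gave as many as the real 11. This share is under 0.05 but was not adjusted over the 6 comparisons. The real count also lay between 1 and 83 without single arrays, so chance is not excluded there. The highest other split gave 126, several times the real count, which may point to a structure of these arrays that was not traced. For the interaction (real 0, highest other 13) and between the days after sham operation (real 0, highest other 56) 100 of 100 splits gave as many, which a real count of 0 fixes in advance, so these splits decide nothing.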

How the results depend on the processing

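The fits without sham replicates 1 and 4 of day 60, those with part of the 21-day transected arrays, the 3' minus 5' covariate for single genes and lists, and the ribosomal list without kinases were chosen after seeing the data.

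The fit of the compared groups alone was not run for the average and the interaction, which use all 4 groups. Each count was within 1.5 times its value under the alternatives, with these exceptions and some without single arrays. With only the probe sets above the median of mean signal, fewer were tested, and 1811 passed at 21 days and 3207 on average. With the 3' minus 5' covariate 98 passed at 60 days, 1873 on average and 4 between the days after transection. At 60 days the differences were smaller and their standard errors 1.48 times as large, but the covariate did not overlap between sham and transected arrays. At 21 days the covariate barely differed between the groups and tests nothing. Between the days after transection 2 passed with centred arrays, 4 with trended and robust eBayes, 2 with array weights, 1 with the compared groups alone and 4 with the glial covariate. Array weights gave 3 for the interaction and 2 between the days after sham operation. Without sham replicates 1 and 4 of day 60, 797 passed at 60 days and 26 between the days after transection. With transected replicates 1 to 4 of day 21 left out 1335 passed at 21 days, 161 for the interaction and 630 between the days after transection, and with replicates 5 to 8 left out 52 did in the last. Fewer arrays were fitted there; beyond this, the cause was not tested.

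Without each array in turn the counts ranged from 2040 to 3177 at 21 days, 1538 to 2760 at 60 days, 4514 to 5303 on average and 1 to 83 between the days after transection, and were 0 for the interaction and between the days after sham operation.

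With the replicate number as a block 3226, 3073, 5347, 0, 10 and 0 passed in the 6 comparisons. Arrays with the same number did not pair: their residuals correlated at a mean r of −0.00372 over 35 pairs (−0.309 to 0.331), and those with different numbers at 0.000288.

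The second probe set of Ccar1 turned the sign at 21 days (0.3172), at 60 days (0.203) and on average (0.2601), and that of Stim1 between the days after transection (−0.05944). The oligodendrocyte list between the sham groups turned with the glial covariate (−0.0044), which holds its own genes, and the matrix (0.0501) and ribosomal lists (0.0361) no longer passed there. Without sham replicates 1 and 4 of day 60 the injury list (0.0135) and the matrix list (−0.0219) turned there; the cause was not tested. Of the differences of named genes, 32 no longer passed with the 3' minus 5' covariate and 150 stayed on their side of the threshold, though some of these moved, such as Gfap at 60 days (0.65 to −0.01). Further, 9 no longer passed with array weights, 8 with the replicate block, 7 with the glial covariate, 5 without sham replicates 1 and 4 and 2 with quantile normalization; 6 came to pass with array weights, 2 with the glial covariate and 2 without sham replicates 1 and 4. The 2 that came to pass with the glial covariate, Aif1 at 21 days and Mbp at 60 days, are themselves part of that covariate. Low signals near the background limit what the arrays can show, and background was not analysed here.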

Other observations

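The genes named here were chosen after their values were seen. Several genes of signalling and defence differed on average over both days in lists that did not pass as a whole. Of all probe sets 39.4% passed by this average, so the counts of members here do not by themselves set a list apart. One probe set of the growth factor gene Nrg1 rose by 1.38 ± 0.197 (adjusted p = 7.44e-06), but of its 3 dimmer ones 1 fell by 0.49 ± 0.111 (adjusted p = 0.00104) and 2 did not pass. The brighter of 2 probe sets of the neurotrophin receptor gene Ntrk2 rose by 0.73 ± 0.157 (adjusted p = 0.00071; the dimmer one did not pass), and Cntf fell by 0.83 ± 0.294 (adjusted p = 0.027, but −0.52 and adjusted p = 0.0698 without sham replicate 1 of day 60); of 31 neurotrophic genes 7 rose and 3 fell, and 6 and 1 when adjusted over the list alone. Without 1 array at a time 5 to 8 of these rose and 1 to 3 fell. Among 21 interferon response genes 4 rose, with Ifi27 at 0.99 ± 0.1 (adjusted p = 4.6e-08), and 5 fell, with Mx2 at −0.76 ± 0.133 (adjusted p = 8.3e-05); 2 to 6 fell without 1 array at a time. Of 15 genes of antigen presentation by MHC class I, 3 rose, among them RT1-CE10 (0.75 ± 0.153, adjusted p = 0.000411), and 2 fell, among them RT1-T24-4 (−1.42 ± 0.193, adjusted p = 3.25e-06). Of 16 complement genes C1qb (0.54 ± 0.119, adjusted p = 0.000792) and Clu (0.63 ± 0.184, adjusted p = 0.00788) rose. Cd55 (−1.64 ± 0.191, adjusted p = 4.14e-07) and C5 (−0.39 ± 0.0836, adjusted p = 0.000626) fell, although the dimmer probe set of Cd55 did not pass (adjusted p = 0.983).

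Calcium handling and cell adhesion genes went both ways on average. Of 26 calcium handling genes 4 rose and 2 fell, and without 1 array at a time 4 to 6 rose and 1 to 3 fell. The protease gene Capn1 rose by 0.47 ± 0.0877 (adjusted p = 0.000157) and Camk2g by 0.80 ± 0.146 (adjusted p = 0.000136). The brightest probe set of Cast, which encodes the inhibitor of the protease, fell by 1.02 ± 0.231 (adjusted p = 0.00112), but a dimmer one rose by 0.30 ± 0.0904 (adjusted p = 0.00974). Of 35 axon guidance genes 8 rose, such as Robo1 (0.36 ± 0.0755, adjusted p = 0.000577), and 3 fell, such as Slit2 (−0.65 ± 0.16, adjusted p = 0.00245); adjusted over the list alone, 6 rose and 2 fell, and without 1 array at a time 5 to 9 rose and 2 to 4 fell. Of 28 apoptosis genes 7 rose, such as Diablo (0.29 ± 0.0555, adjusted p = 0.000216), and 3 fell, such as Mcl1 (−0.34 ± 0.112, adjusted p = 0.0186); without 1 array at a time 5 to 8 rose and 3 to 5 fell. Of 14 interneuron markers Slc17a6 fell (−0.69 ± 0.228, adjusted p = 0.0179), as did the brighter probe set of Gad1 (−1.33 ± 0.459, adjusted p = 0.0226, but 0.0621 without sham replicate 4 of day 60), though not the dimmer one (adjusted p = 0.189).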
